A study of Mus musculus with 12 samples.

How the data were processed

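Cortex mRNA of 12 mice was measured by RNA sequencing, 6 wild-type mice and 6 homozygotes for the Y446C allele of Tbl1xr1, with 3 females and 3 males of each genotype. Per the labels, RNA was prepared from frozen cortex with TriReagent and a column kit, libraries were made with the Kapa mRNA HyperPrep kit, and paired reads of 150 bases were sequenced on an Illumina NovaSeq. Per the labels, reads were trimmed with Trimmomatic 0.36, aligned to GRCm38.p6 with HISAT2 2.1.0 and counted with HTSeq 0.11, and Cufflinks is named without a version. The deposited table holds raw read counts per gene and library, as whole numbers. The strand setting of the counting and the annotation release are not given in the sources used here, so counts of genes that overlap on opposite strands are uncertain. Of 54232 gene identifiers, 54165 matched GENCODE M21, and the 67 others held at most 0.0297% of a library's counts. All columns carry 1 lane name, and the labels give no library or sequencing batch. No paired analysis was possible because the groups share no animal number.

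Counts assigned to genes ran from 3748515 in female mutant 3 to 32669138 in female mutant 6. The floor for a count of 0 was set at 3 counts per library, and it covers counting error alone. Between libraries of 1 group, the chi-square per degree of freedom of the counts was 9.01 to 153, so the spread between mice exceeded counting error.

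Genes were kept by edgeR's filterByExpr over the 4 groups, which left 18016. Counts were scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with sex and genotype as terms for the effects over both sexes, and with 1 mean per group for the effect in females, the effect in males and their difference. P values were adjusted by Benjamini-Hochberg over all tested genes of a comparison and called at 0.05. Values per library are CPM on TMM-scaled totals, and log2 CPM used a prior count of 2.

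Before the data were examined, 30 gene lists were fixed, 17 of pathways, 7 of cell types and 6 of other tissues, along with 1 list of sex-linked genes to check the labels. The 30 lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01, and again with the correlation estimated from the data. A list needed at least 3 tested genes. Calls of members are given over all genes and adjusted over the list alone. Genes within 10 Mb of Tbl1xr1 were compared with the others by a one-sided Fisher's exact test.

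The genes named were chosen by a rule fixed at the same time: Tbl1xr1 and its complex, then the called genes of largest change or, with fewer than 5 called in a direction, the 5 of smallest p. These had a mean of at least 1 CPM, a symbol that is neither provisional nor of a pseudogene and, over both sexes, the same sign in females and males. The rule adds the sex-linked check list, the 5 autosomal genes of smallest p for sex, and the 4 members of smallest p in each called list, of which some are not reported. Other genes named are said to be chosen after their values were seen.

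The alternatives fixed in advance were DESeq2 1.42.0, limma-voom, limma-voom with library weights, scaling by RLE or by library totals, no filter, a filter of 1 CPM in 6 libraries, a tissue component as a covariate, no sex term, 1 mean per group, each sex alone, windows of 5 and 20 Mb, the estimated correlation, and leaving out each of the 12 libraries. After the data were seen, the mitochondrial share was added as a covariate, and DESeq2, the weighted fit and the estimated correlation were repeated without female mutant 3. Leaving out libraries in the list tests of each sex and of the interaction, and exact permutations of genotype within sex (400 labellings), were also added then, as were Fisher's test of genes at an unadjusted p under 0.05 and the relation of the channel list to the striatal list over libraries. Where a library was left out, its group kept 2 libraries, and the spread was pooled over all groups.

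The procedure was tested on simulated data with 50 genes changed at each fold. Over both sexes it recovered 40% of genes changed 1.5-fold, 70% at 2-fold and 100% at 4-fold, with 6 unchanged genes among 113 calls. In females it recovered 4%, 32% and 84%, with 7 unchanged among 68. In males it recovered 2%, 38% and 78%, with 5 unchanged among 64. For the interaction it recovered 0%, 8% and 68%, with 2 unchanged among 40, and for sex 42%, 76% and 96%, with 7 unchanged among 114. Camera called the 1 list that was shifted, by 0.3 on the log2 scale, and 0 others. The simulated genes were drawn independently of one another. This check therefore could not show how often the preset calls unshifted lists whose members are correlated.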

Results

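Messenger RNA of the cortex was profiled in 12 C57BL/6J mice aged 12 weeks. Homozygotes for the Y446C allele of Tbl1xr1, a model of Pierpont syndrome, numbered 6, and wild-type mice numbered 6, with 3 females and 3 males of each genotype. Tbl1xr1 encodes a subunit of the NCoR corepressor complex, which represses the targets of nuclear receptors such as the thyroid hormone receptor. Libraries are named here by sex, genotype and animal number. In 11 libraries the counts assigned to genes ran from 21238427 to 32669138, with a median of 24712815, and mitochondrial genes took 5.23% to 10.4% of them. Female mutant 3 stood apart with 3748515 counts, a mitochondrial share of 31.6% and 17349 genes with a count, against 24346 to 26012 genes in the others. Its median Spearman correlation with the other libraries was 0.921, whereas the other libraries correlated with one another at 0.985 to 0.994, and the first principal component, which held 68.9% of the variance, set it apart. A count of 0 allowed a level of up to 0.0861 to 0.137 CPM (counts scaled to a library of 1e+06) in the 11 libraries and up to 1.16 CPM in female mutant 3, and these floors cover counting error alone.

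**Figure D1:**
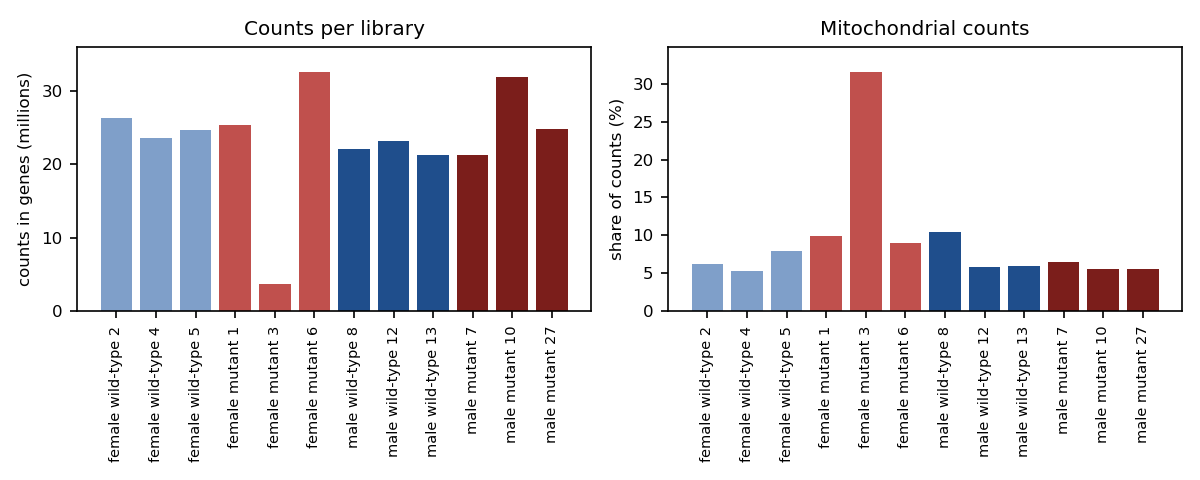
Counts assigned to genes, in units of 1e+06 counts (left) and mitochondrial share of counts in percent (right), 1 bar per library, coloured by sex and genotype. Female mutant 3 held 3748515 counts, 31.6% of them mitochondrial, and the other libraries held 21238427 to 32669138.

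The mutated gene itself was read first. Tbl1xr1 (ENSMUSG00000027630, chromosome 3, 22076652 to 22216594, GRCm38) stood at 105 ± 7.05 CPM in wild-type and 93.5 ± 2.69 CPM in mutant cortex (SD, n = 6), a log2 fold change of -0.17 (SE 0.07) that did not pass edgeR's quasi-likelihood test (adjusted p = 0.950). Its transcript was thus present in the mutants at a level near that of the wild type, and since the counts carry no sequence, they do not check the genotype labels. In the reference transcript, the changed residue is encoded by the TAC codon at 22203912 to 22203914 in exon 14 of 16, and the labels name the change as Y446C. Of the partners in the complex, Ncor1 (log2 fold change 0.16), Gps2 (0.35), Hdac3 (-0.07) and Tbl1x (-0.06) did not pass the test either. The library labelled female mutant 3 held the highest CPM of Ncor1, Gps2 and Tbl1x among the mutants, at 566, 27.1 and 132 CPM. A pseudogene lies on the other strand within Tbl1xr1, and the counting is not stated to use strand.

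The series sets mutant against wild-type cortex to find the genes and pathways that the mutation alters. Over both sexes, Mpeg1 fell to 0.484 of its wild-type level. Mpeg1 encodes perforin-2, a pore-forming protein of macrophages and microglia. Its level was 25.8 ± 2.19 CPM in wild-type and 12.1 ± 2.64 CPM in mutant mice (SD, n = 6), and the highest mutant library (14.6 CPM) lay below the lowest wild-type library (23.2 CPM). The change had a like size in females (log2 fold change -1.09) and males (-1.001). Mpeg1 (ENSMUSG00000046805, chromosome 19, 12460779 to 12465283) overlaps no other annotated gene.

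Of 18016 genes tested with edgeR's quasi-likelihood test over both sexes, Mpeg1 alone passed the threshold, with 0 genes higher and 1 lower (log2 fold change -1.05, SE 0.12, adjusted p = 0.0257). At an unadjusted p under 0.05 there were 713 genes, against 901 that evenly spread p values would give. Limma-voom called 1 gene, DESeq2 29 (9 higher, 20 lower) and limma with library weights 22 (6 higher, 16 lower), with 17 genes called by both of the latter tools. These counts depended on female mutant 3, without which DESeq2 called 53 (20 higher, 33 lower) and the weighted fit 4 (2 higher, 2 lower), and 4 genes were called by both tools with and without it. The edgeR call of Mpeg1 was lost when any 1 of the 11 libraries other than female mutant 3 was left out (adjusted p = 0.0866 to 0.180, log2 fold change -1.09 to -0.99), and without female mutant 3 it was 0.000693, within a range of 4.52e-21 to 0.532 over all 25 alternatives.

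The naming rule took the 5 genes of smallest p on each side, and those other than Mpeg1 are given with their values, although none passed edgeR's test. They are not the overall ranking, since C1ra (edgeR adjusted p = 0.577), on the lower side, ranked above Plce1. Bcl6, a transcriptional repressor that recruits the NCoR corepressor, stood at 30.7 ± 1.69 CPM in wild-type and 40.1 ± 4.02 CPM in mutant mice (SD, n = 6; edgeR adjusted p = 0.577). Dlk1, an imprinted gene related to Notch ligands, stood at 16.0 ± 6.04 and 33.9 ± 9.12 CPM, and Zim1, an imprinted zinc finger gene, at 12.5 ± 2.39 and 19.1 ± 2.16 CPM. The co-chaperone gene Bag3 (log2 fold change 0.43) and the phospholipase gene Plce1 (0.45) were the others on the higher side. On the lower side stood Cyp4f15, a cytochrome P450 of fatty acid oxidation (8.53 ± 1.33 and 4.97 ± 0.811 CPM), the adrenergic receptor gene Adra1a (17.7 ± 0.723 and 13.6 ± 0.645 CPM), the guanylate cyclase subunit gene Gucy1a2 (25.5 ± 1.77 and 19.4 ± 1.48 CPM) and the inhibitory Fc receptor gene Fcgr2b (3.59 ± 0.683 and 2.07 ± 0.767 CPM). In edgeR their adjusted p ran from 0.577 for Bcl6, Bag3, Cyp4f15, Adra1a, Gucy1a2 and Fcgr2b to 0.857 for Plce1. DESeq2 called all 9 of these genes, and over the alternatives the adjusted p of Adra1a ran from 0.000197 to 0.9998 and that of Dlk1 from 0.0156 to 0.9998. Annotated genes on the other strand overlap Fcgr2b, Plce1 and Bcl6, and a gene on the same strand overlaps Bag3, so the counts of these genes are uncertain.

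**Figure D2:**
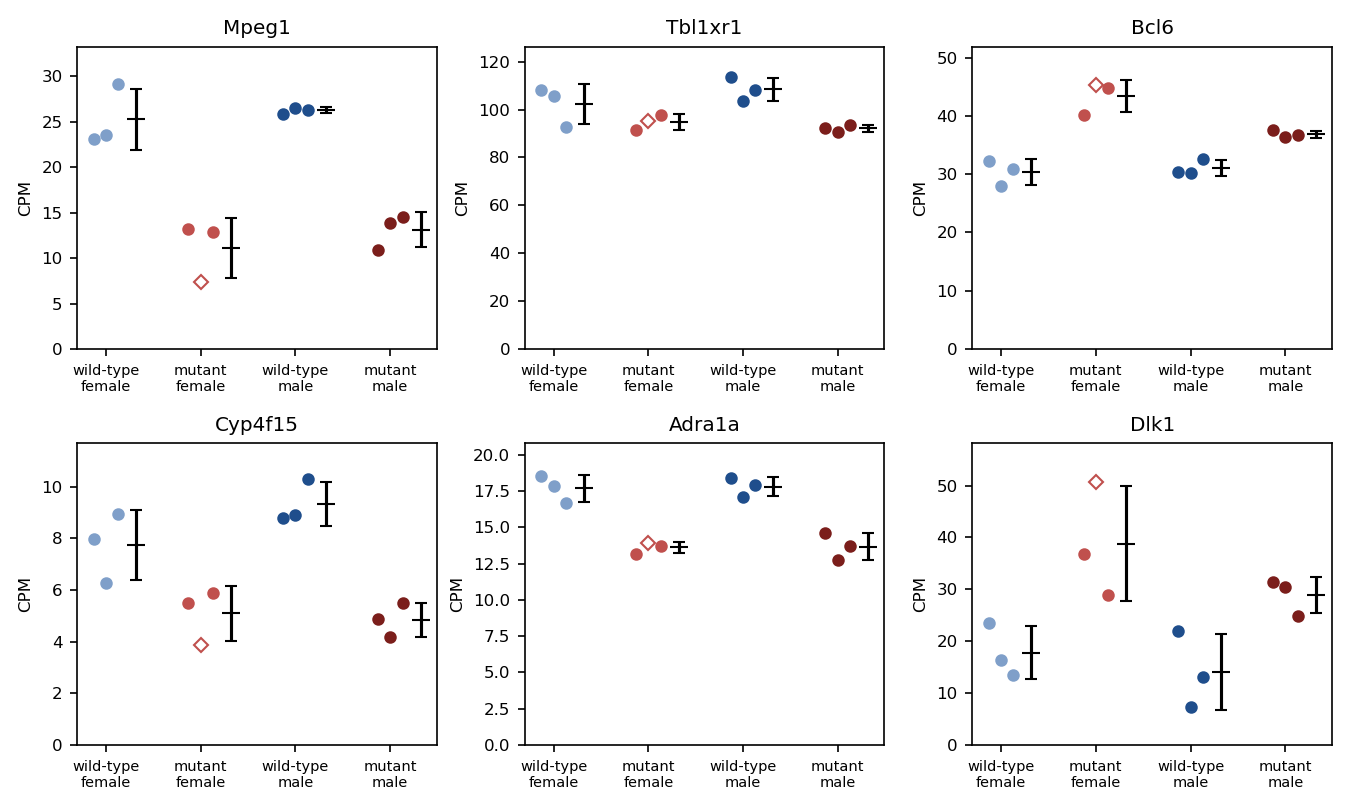
CPM of Mpeg1, Tbl1xr1, Bcl6, Cyp4f15, Adra1a and Dlk1 in each library (points), with the mean and SD of the 3 libraries of each group (bars), and the open diamond for female mutant 3. Mpeg1 reached at most 14.6 CPM in a mutant and at least 23.2 CPM in a wild-type library.

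Among 30 fixed gene lists, 4 passed limma's camera test with the preset correlation over both sexes, 1 up and 3 down, and 0 passed with an estimated correlation. Markers of striatal neurons, which belong to a neighbouring region, fell as a list: 12 of 12 were lower in mutants, with a median log2 fold change of -0.79 (adjusted p = 2.90e-09 with the preset, adjusted p = 0.636 with an estimated correlation). Syndig1l, Ppp1r1b, Adora2a and Gpr6 had the smallest p. Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, stood at 188 ± 87.0 CPM in wild-type and 105 ± 30.5 CPM in mutant mice (SD, n = 6), and Adora2a, an adenosine receptor gene, at 35.4 ± 17.9 and 16.3 ± 7.50 CPM. With edgeR, 0 striatal genes passed over all genes and 5 passed, all lower, when adjusted over the list alone. The mean of the list, taken on the log scale, varied 7.39-fold between the highest and the lowest library.

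Voltage-gated sodium, potassium and calcium channel genes fell as a list, with 19 of 27 lower and a median of -0.07 (camera adjusted p = 0.0198 with the preset, adjusted p = 0.261 with an estimated correlation). Their estimated correlation of 0.00644 lay below the preset of 0.01, yet camera's unadjusted p rose from 0.00132 to 0.00871. A higher correlation among the channel genes therefore does not explain the loss of their call, and its cause was not tested. The sodium channel subunit gene Scn4b had the smallest p, with 220 ± 94.6 CPM in wild-type and 119 ± 38.6 CPM in mutant mice (SD, n = 6), and Cacna1g (log2 fold change -0.47) and Cacna1i (-0.34) were also lower, neither past edgeR's test. The channel list moved with the striatal list over the 12 libraries (Pearson's r = 0.760, permutation p = 0.00307; Spearman's rho = 0.790, permutation p = 0.00343; r = 0.796 without the 2 libraries farthest in the striatal list). With the mean of each group removed, r was 0.769 (permutation p = 0.00349) and rho 0.797 (permutation p = 0.00297). The adjusted p of these 2 relations was 0.00349 for each r and 0.00343 for each rho. The permutation shuffled all 12 residuals freely, although they sum to 0 within each group. Its p with group means removed is therefore likely too small, as are the adjusted p that draw on it, and only r and rho are read. Microglia markers fell as a list, with 11 of 12 lower and a median of -0.14 (adjusted p = 0.0330 with the preset, adjusted p = 0.636 with an estimated correlation). The mean log2 CPM of that list over libraries differed by -0.19 (SE 0.10), and by -0.09 without female mutant 3, the lowest library for it. The microglial receptor genes Trem2 (-0.36), Cx3cr1 (-0.17) and Csf1r (-0.20) were lower and P2ry12 (0.34) was higher, none of them past edgeR's test. Genes of endoplasmic reticulum and heat stress rose as a list, with 10 of 16 higher and a median of 0.12 (adjusted p = 0.0365 with the preset, adjusted p = 0.739 with an estimated correlation). The chaperone genes Calr (0.23), Hsph1 (0.22), Hsp90b1 (0.23) and Dnajb9 (0.27) led it, while the mean log2 CPM of the list over libraries differed by -0.003 (SE 0.170), and by 0.13 without female mutant 3, the lowest library for this list. In these 3 lists, 0 members passed edgeR's test over all genes and 0 when adjusted over the list alone. Members at an unadjusted p under 0.05 numbered 2 among the channels, 1 among the microglia markers and 0 among the stress genes.

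The striatal call held without each of the 12 libraries. The channel call was lost without female mutant 1 (adjusted p = 0.0593), male wild-type 8 (0.0598), male mutant 10 (0.0783) or male wild-type 12 (0.101). The microglia call was lost without female mutant 1 (0.0696), female wild-type 5 (0.0946), male mutant 10 (0.0848) or male wild-type 12 (0.0839). The stress call was lost without female mutant 1 (0.0710), female wild-type 4 (0.105), female mutant 6 (0.0879), male mutant 7 (0.0933) or male wild-type 8 (0.547). These are camera values with the preset correlation.

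**Figure D3:**
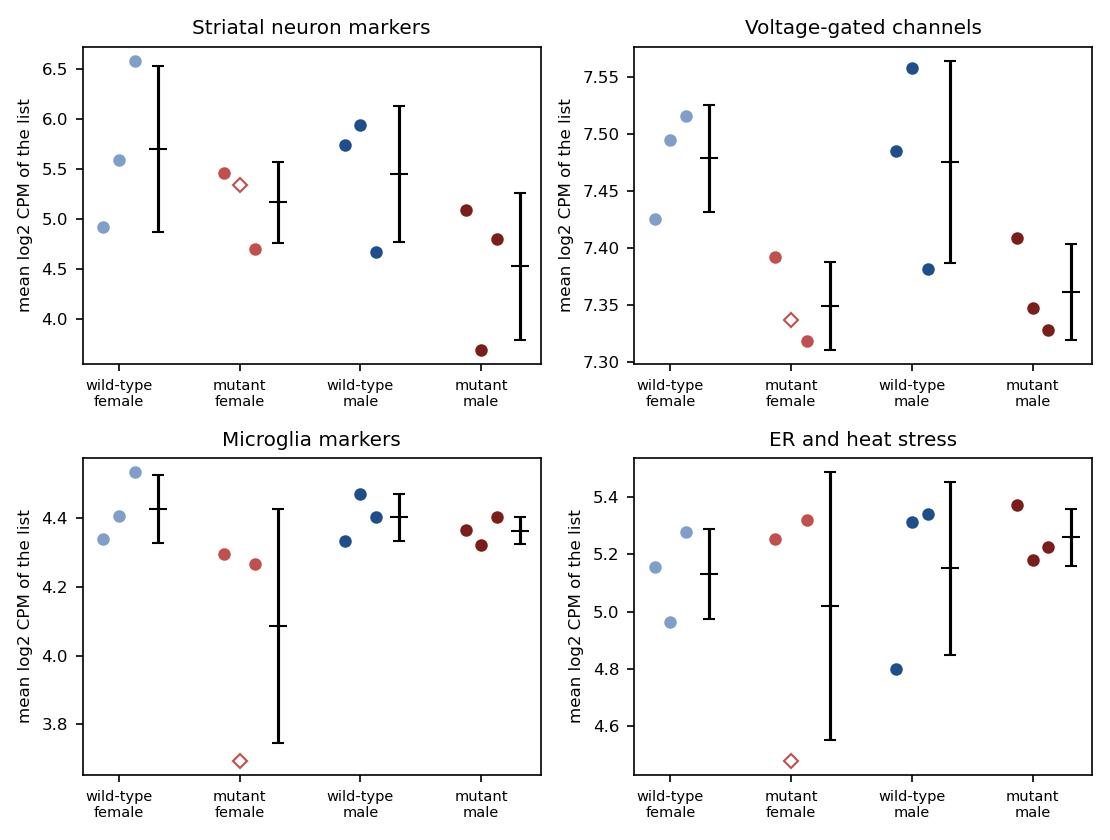
Mean log2 CPM of the 4 gene lists that passed camera's preset test over both sexes, per library (points), with the mean and SD of 3 libraries per group (bars), and the open diamond for female mutant 3. The striatal list spread over 7.39-fold between libraries, and female mutant 3 was the lowest library for the microglia and stress lists.

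The other lists did not pass camera's preset test over both sexes. Of the lists tied to the corepressor, its own complex (adjusted p = 0.416), thyroid hormone-induced genes (0.190), LXR and PPAR targets (0.279), retinoic acid targets (0.494), Notch targets (0.587), Wnt targets (0.106), NF-kappaB targets (0.587) and the circadian clock (0.318) leaned down. Of the cell types, excitatory (0.0697) and inhibitory neurons (0.0583) leaned down, astrocytes (0.0624) and oligodendrocytes (0.587) up, and oligodendrocyte precursors (0.949) and endothelial and mural cells (0.521) down. Glutamate receptors gave 0.521, GABA receptors 0.808, immediate-early genes 0.449, interferon-stimulated genes 0.494, respiratory chain subunits 0.808, ribosomal proteins 0.239 and cholesterol synthesis 0.106. Of the other tissues, the meninges gave 0.279, the choroid plexus 0.106, the hippocampus 0.175, the thalamus 0.587 and blood 0.260. Adjusted over the list alone, edgeR called Cyp4f15 among the LXR and PPAR targets, 1 Wnt target, 1 hippocampal marker (each lower) and 2 astrocyte markers (higher). The sign of the test and that of the median differed for immediate-early genes, glutamate receptors, GABA receptors, respiratory chain subunits, ribosomal proteins and thalamic markers, and the mean of the NCoR complex (0.01) differed in sign from its median (-0.06).

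In females alone, Mpeg1 had the smallest p among the lower genes, with 25.3 ± 3.34 CPM in wild-type and 11.1 ± 3.29 CPM in mutant mice (SD, n = 3), followed by Lsp1, a leukocyte protein gene (log2 fold change -1.24), Pamr1 (-0.68), Gucy1a2 (-0.47) and the growth factor gene Hbegf (-0.58). On the higher side stood Bcl6 (30.4 ± 2.22 and 43.4 ± 2.78 CPM), the growth factor gene Tgfb2 (20.1 ± 2.91 and 32.7 ± 5.47 CPM), Cpne4 (0.59), Bex2 (0.52) and the imprinted cell cycle inhibitor gene Cdkn1c (1.06). None of these passed edgeR's test (adjusted p = 0.418 for each). EdgeR called 0 genes in females, with 2127 at an unadjusted p under 0.05 against 901 expected, and limma-voom 0, DESeq2 6 (5 higher, 1 lower) and limma with library weights 4 (3 higher, 1 lower). Without female mutant 3 DESeq2 called 15 in females (8 higher, 7 lower) and the weighted fit 1. EdgeR's fit pooled the spread over all 4 groups. Female mutant 3 differed from female mutants 1 and 6 by a chi-square per degree of freedom of 136 and 153. Same-group pairs without it gave 9.01 to 39.8. With such unequal spread, 901 need not be the number chance gives in females, in males or for the interaction. The 2127 genes are therefore no evidence of an effect of genotype in females. Mitochondrial counts took 9.96%, 31.6% and 8.97% in female mutants 1, 3 and 6 against 5.23% to 7.89% in the 3 wild-type females, so this share was higher in every mutant female, whereas in males it was 5.57% to 6.51% in mutants and 5.79% to 10.4% in wild-type mice. Scaling by library totals in place of TMM moved the median log2 fold change of all genes in females from -0.03 to -0.21. Blood cell markers fell as a list in females (5 of 5 lower, camera adjusted p = 0.0117 with the preset, adjusted p = 0.923 with an estimated correlation), with edgeR calling 0 members over all genes and 1, lower, when adjusted over the list alone. The list's call was lost without female mutant 6 (adjusted p = 0.257). Without female mutant 3 the number of lists called rose from 1 to 6. It was 2 without female mutant 1, 4 without female wild-type 2 or female wild-type 4, 2 without female wild-type 5, male wild-type 8, male mutant 10 or male wild-type 13, and 0 without female mutant 6.

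In males alone, the globin genes Hba-a1 (5.46 ± 0.437 CPM in wild-type, 10.5 ± 1.24 CPM in mutant mice) and Hbb-bs (14.1 ± 3.15 and 28.0 ± 4.02 CPM; SD, n = 3) led the higher genes with Stac (log2 fold change 1.08), Lgi4 (0.59) and Rftn1 (0.48). On the lower side stood Mpeg1 (26.3 ± 0.333 and 13.1 ± 1.93 CPM), Cyp4f15 (9.32 ± 0.849 and 4.84 ± 0.668 CPM), the lipoprotein lipase gene Lpl (29.4 ± 2.06 and 19.2 ± 2.14 CPM), Fcgr2b (-1.15) and the complement protease gene C1ra (-1.42). None of these passed edgeR's test (adjusted p = 0.9999 for each). EdgeR called 0 genes in males, with 501 at an unadjusted p under 0.05 against 901 expected, and limma-voom 0, DESeq2 4 (1 higher, 3 lower) and limma with library weights 1. Without female mutant 3, which enters this fit through the shared spread, edgeR called 1 gene, Mpeg1, in males (adjusted p = 0.0338, within 6.40e-10 to 1 over the alternatives), DESeq2 16 (7 higher, 9 lower) and the weighted fit 1. The globin genes have near-identical copies, between which the counting could split reads.

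By camera with the preset correlation, 14 lists passed in males, 7 up and 7 down, and 0 passed with an estimated correlation (adjusted p = 0.0893 to 0.752 with an estimated correlation). The estimate lay below the preset for inhibitory neuron markers (-0.0252) and the NCoR complex (-0.00185), and above it for the other called lists. A higher correlation therefore does not explain the loss of the calls of inhibitory neuron markers and the NCoR complex. Blood cell markers rose, with 5 of 5 higher (adjusted p = 5.22e-10), as did cholesterol synthesis, with 18 of 18 (8.46e-04), respiratory chain subunits, with 32 of 36 (5.19e-04), ribosomal proteins, with 38 of 43 (5.19e-04), immediate-early genes, with 13 of 17 (0.0276), meningeal markers, with 9 of 11 (0.0242), and astrocyte markers, with 9 of 12 (0.0387). Striatal markers fell, with 12 of 12 lower (5.76e-09), as did excitatory neuron markers, with 11 of 14 (8.46e-04), inhibitory neuron markers, with 10 of 13 (0.00196), channels, with 23 of 27 (0.00518), the NCoR complex, with 5 of 6 (0.0137), hippocampal markers, with 8 of 11 (0.0233), and GABA receptors, with 13 of 14 (0.0242). Examples are the sterol synthesis gene Sqle (log2 fold change 0.30), the interneuron genes Lhx6 (-0.40) and Gad1 (-0.22), and Gfap (0.51). EdgeR called 0 members of the 14 lists over all genes, and 4 blood cell genes, higher, when adjusted over the list alone.

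Of the 14 lists in males, 6 kept their call without each library, namely blood, striatal, inhibitory, cholesterol synthesis, respiratory chain and the NCoR complex. Without male mutant 10 the calls of GABA receptors (camera adjusted p = 0.249), excitatory neurons (0.163), astrocytes (0.466) and meninges (0.411) were lost. Without male wild-type 12 those of GABA receptors (0.0787), channels (0.250), astrocytes (0.318) and meninges (0.936) were lost, and without male wild-type 8 those of GABA receptors (0.0885), immediate-early genes (0.642) and ribosomal proteins (0.0515). Hippocampal markers lost it without male wild-type 13 (0.230) or male mutant 27 (0.354), and immediate-early genes without male mutant 7 (0.184) or male mutant 27 (0.603). Astrocytes (0.102) and meninges (0.0637) lost it without female mutant 3, and astrocytes without female mutant 1 (0.0502).

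Whether the mutation acts differently in the sexes was tested by the interaction, the male effect minus the female effect. Globin genes crossed: Hbb-bs stood at 24.4 ± 2.74 CPM in wild-type and 13.4 ± 5.08 CPM in mutant females, against 14.1 ± 3.15 and 28.0 ± 4.02 CPM in males (SD, n = 3), and Hba-a1 at 9.01 ± 1.66 and 6.80 ± 1.20 CPM against 5.46 ± 0.437 and 10.5 ± 1.24 CPM. The differences of log2 fold change were 1.78 (SE 0.33) for Hbb-bs and 1.32 (SE 0.26) for Hba-a1. The monocarboxylate transporter gene Slc16a1 (0.54), Itm2a (0.67) and Smim26 (1.053) shared their sign, and Ccbe1 (-0.86), Trdn (-4.74), Stxbp6 (-0.69), Lpl (-0.61) and Mndal (-1.38) had the other. None passed edgeR's test (adjusted p = 0.555 for each). EdgeR called 0 genes, with 1381 at an unadjusted p under 0.05 against 901 expected, and limma-voom 0, DESeq2 4 and limma with library weights 1 (4 and 0 without female mutant 3). Without female mutant 6, edgeR called 1 gene, Trdn (adjusted p = 0.0233, within 0.0233 to 0.983 over the alternatives), which several annotated pseudogenes overlap and which stood at 0.147 CPM in mutant males.

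**Figure D4:**
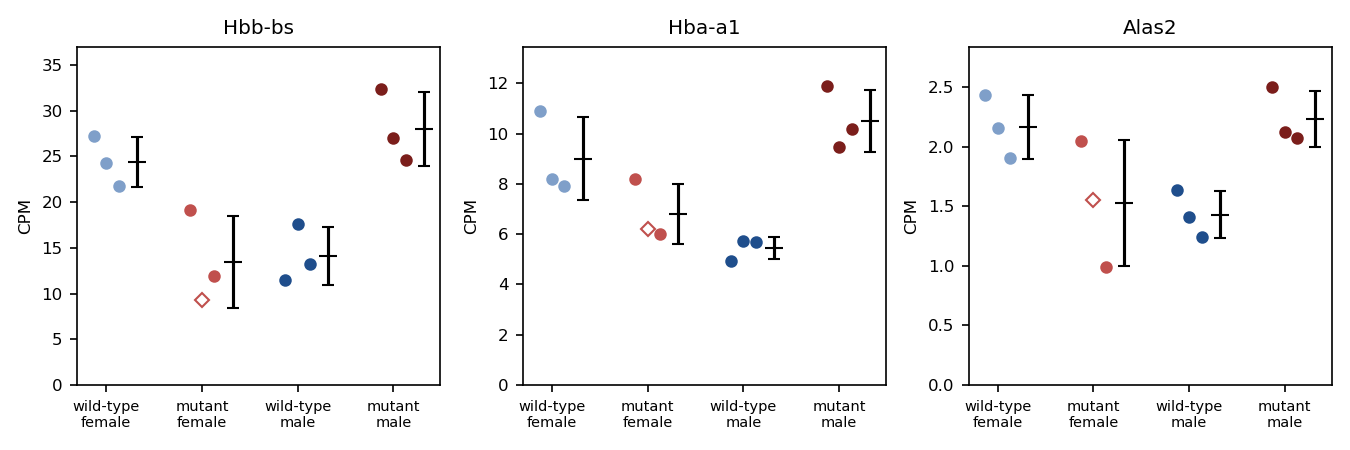
CPM of the globin genes Hbb-bs and Hba-a1 and of Alas2, a gene of haem synthesis in red cells, in each library (points), with the mean and SD of 3 libraries per group (bars), and the open diamond for female mutant 3. Hbb-bs averaged 24.4 and 13.4 CPM in wild-type and mutant females, and 14.1 and 28.0 CPM in wild-type and mutant males.

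For the interaction, 4 lists passed camera with the preset correlation and 0 with an estimated correlation. Blood cell markers had a more positive effect in males (5 of 5, median 1.55, adjusted p = 2.06e-07, adjusted p = 0.279 with an estimated correlation), as had respiratory chain subunits (26 of 36, median 0.30, adjusted p = 6.30e-04, adjusted p = 0.735 with an estimated correlation) and ribosomal proteins (31 of 43, median 0.39, adjusted p = 0.0381, adjusted p = 0.788 with an estimated correlation). GABA receptors had a more negative one (11 of 14, median -0.31, adjusted p = 0.0457, adjusted p = 0.735 with an estimated correlation). EdgeR called 0 members over all genes, and 5 blood cell genes, all more positive in males, when adjusted over the list alone. Camera's call of ribosomal proteins was lost without female wild-type 5 (adjusted p = 0.0551), male wild-type 8 (0.0671) or male mutant 10 (0.0542). That of GABA receptors was lost without female wild-type 2 (0.0541), female wild-type 4 (0.0517), female mutant 3 (0.0910), male mutant 10 (0.1102) or male wild-type 12 (0.100), and female mutant 3 had the highest mean of that list and the lowest of ribosomal proteins among the mutants.

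The female and male effects compared across the 18016 genes gave a correlation of -0.122 (Pearson's r) and -0.229 (Spearman's rho), and 38.0% of genes shared a sign. Genes are not independent replicates, and this value rested on female mutant 3, without which r was 0.0204 and 46.2% shared a sign. It also changed sign without male wild-type 8 (0.0466) and was -0.0489 without male mutant 10, -0.0567 without female wild-type 2, -0.0829 without female wild-type 4 and -0.0791 without male mutant 27. At an unadjusted p under 0.05 in both sexes there were 59 genes, where independence gives 59.1, and 41 of the 59, Mpeg1, Cyp4f15, Gucy1a2 and Fcgr2b among them, had the same sign. EdgeR called 0 genes in either sex, so no overlap of calls could be counted.

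Sex itself served as a check of the labels. The Y-linked genes Kdm5d, Uty, Ddx3y, Eif2s3y and Gm29650 were higher in males, and the X-linked Xist and Eif2s3x were higher in females. EdgeR called these 7 genes (5 higher and 2 lower in males, 319 at an unadjusted p under 0.05 against 901 expected). Kdm5d ran from 37.9 to 43.8 CPM in males and from 0 to 0.118 CPM in females, and Xist from 836 to 1093 CPM in females and from 0.154 to 2.23 CPM in 5 males and 19.6 CPM in male mutant 7, whose higher level was not explained. By these genes, all 12 libraries matched the sex of their labels. The autosomal genes with the smallest p were Endog (log2 fold change 0.59), Rgs22 (-0.63), Dnali1 (-0.65), Tle2 (0.55) and Teddm2 (0.42), none past edgeR's test (adjusted p = 0.897 for each). Limma-voom called 7 genes, limma with library weights 10 and DESeq2 12.

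Homozygous mutants can share a haplotype around the edited gene, so the genes near Tbl1xr1 were tested as a set. Of 58 tested genes within 10 Mb, edgeR called 0, since its 1 call, Mpeg1, lay elsewhere. With 0 calls in the window, the one-sided test of calls could give no other p than 1. At an unadjusted p under 0.05 there was 1 of 58 genes, against 712 of 17958 elsewhere (one-sided Fisher's exact p = 0.904, a test added after the data were seen). With the window at 5 Mb (24 genes) or 20 Mb (156 genes), edgeR also called 0, with 0 and 3 genes at an unadjusted p under 0.05. Neither DESeq2, limma-voom nor limma with library weights called a gene within 10 Mb over both sexes.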

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

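Several tests here were chosen only after the result was seen: those of the microglia list and of leaving out female mutant 3 for Mpeg1, those of correlated residuals and of leaving out female mutant 3 for the striatal list, and the permutation test of the haemoglobin genes.

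Female mutant 3 lay far from the other mutants. Measures were examined over the 6 libraries of each genotype, which gave 100 sets of 6 values. In 19 sets the gap of a library to its neighbour, divided by the range, exceeded Dixon's 95% critical value. Of the 19, 17 concerned female mutant 3. Chance flags about 1 in 20 independent sets, which is 5 of 100, but these sets share libraries. The 17 are therefore not separate findings. Its mitochondrial share of 31.6% gave a ratio of 0.831, its 17349 genes with counts 0.808 and its TMM factor of 0.690 gave 0.740. Its Ncor1 level was 566 CPM against 301 to 371 CPM (0.738), Gps2 27.1 against 10.2 to 15.5 CPM (0.689) and Tbl1x 132 against 81.5 to 96.0 CPM (0.713), so the means of these corepressor genes in mutants rested in part on this library. GABA receptors stood higher in it (0.643). Lower in it were thyroid hormone-induced genes (0.840), LXR and PPAR targets (0.827), retinoic acid targets (0.882), Notch targets (0.907), Wnt targets (0.718), ribosomal proteins (0.845), cholesterol synthesis (0.762), endoplasmic reticulum and heat stress genes (0.784), oligodendrocyte precursor markers (0.822) and microglia markers (0.808). In wild-type mice, female wild-type 2 was high for choroid plexus markers (0.628) and male wild-type 8 for Ncor1, at 370 CPM against 306 to 329 CPM (0.643).

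The effect of genotype differed between the sexes by camera's preset test of the interaction for blood cell markers (adjusted p = 2.06e-07), respiratory chain subunits (6.30e-04), ribosomal proteins (0.0381) and GABA receptors (0.0457). With an estimated correlation the adjusted p was 0.279, 0.735, 0.788 and 0.735.

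Mpeg1 was lower in all 6 mutants than in any wild-type mouse, by -1.05 on the log2 scale. The microglia list had a median of -0.14 with an SD of 0.17 over its 12 members, which argues against a loss of microglia as the whole cause. The tests also argue against a loss of border macrophages, of whose 10 fixed markers the 6 tested had a median of 0.0327 with an SD of 0.27. They argue against female mutant 3, since without it the adjusted p was 0.000693, within 4.52e-21 to 0.532 over the alternatives. A variant linked to Mpeg1 and shared by the mutants may remain a cause: within 5 Mb, 1 of 93 genes had an unadjusted p under 0.05 (one-sided Fisher's exact p = 0.977), but a variant in Mpeg1 alone would leave no such trace, and an effect of the mutation stays open beside it.

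Striatal markers were lower in the mutants as a list by camera's preset (adjusted p = 2.90e-09), a call that was lost with the estimated correlation of 0.907 (adjusted p = 0.636). Within groups the members rose and fell together, with a mean correlation of residuals of 0.890 over all libraries. Without female mutant 3 it was 0.951, against a 95th percentile of 0.0983 in 1000 random lists, also taken without that library. Varying amounts of striatal tissue in the samples would give such a correlation. Female mutant 3 is argued against as the cause of the lower mean: without it the difference of the list mean was -0.77, against -0.73 with all libraries (jackknife SE 0.46, range -0.92 to -0.51), and its own mean of 5.34 log2 CPM lay above the mean of the 5 other mutants (4.75, SD 0.66). A difference between genotypes beyond the spread between mice stays open: the list mean was 5.57 ± 0.69 log2 CPM in wild-type and 4.85 ± 0.64 in mutant mice (SD, n = 6), a difference of -0.73 (SE 0.39), with an exact permutation p of 0.085 (34 of 400 labellings, two-sided). The bound written beforehand would have excluded that difference at p of 0.05 or more, and after the value was seen it was judged wrong, because a p that misses the threshold does not show that values did not differ.

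Haemoglobin genes were lower in mutant females (-0.94 for the globin mean, and -0.59 without female mutant 3) and higher in mutant males (0.99). Over 12 libraries the red-cell genes Alas2 and Slc4a1 followed the globins (Pearson's r = 0.849, permutation p = 0.00028, Spearman's rho = 0.839, permutation p = 0.00107, and r = 0.930 without the 2 farthest libraries). Varying residual blood would give such a relation, although Slc4a1 had 41 counts in all. Alas2 was itself a member of the blood cell list that crossed, and group means were not removed. An effect of genotype and sex on red-cell genes would give this relation too, so it does not decide. Female mutant 3 is argued against as the cause: without it the male minus female effect was 1.58, against 1.93 with all libraries (jackknife SE 0.54, range 1.58 to 2.29). An exact permutation within sex gave p = 0.01 (4 of 400 labellings, two-sided) but the globins were singled out for this difference, so that p does not count for it, and a difference beyond the spread between mice stays open. Mice were killed by exsanguination per the labels, and whether blood removal or red-cell content differed was not tested.

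Other splits of the same samples were counted. Over both sexes the real split gave 1 called gene and the highest other split 0. With 1 of 100 splits as large, the real one included, this argues against chance for that count. It does not exclude chance, since 1 of 100 is the smallest share that 100 splits can give. The count also rests on Mpeg1 alone, which kept its call in 12 of 25 alternatives. For sex the real value was 7 and the highest other 1 (1 of 100), which argues against chance there too. For the interaction the real count was 0 and the highest other 1 (100 of 100), and since every split reaches a count of 0, this says nothing about chance. In females and in males the real count was 0 and the highest other 0 (10 of 10), and 10 splits are too few for a share under 0.05. For the lists the real count was 4 and the highest other 14, with 86 of 100 splits as large, so chance cannot be excluded for the number of lists called by the preset. The many lists called in other splits could come from a structure of the samples or from a preset of 0.01 below the lists' own correlation (0.907 estimated for striatal, 0.791 for blood cell and 0.142 for microglia markers, but 0.00644 for channels), and these were not tested apart.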

How the results depend on the processing

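The mitochondrial share as a covariate, and DESeq2, the weighted fit and the estimated correlation without female mutant 3, were tests chosen only after the results were seen. Unless said otherwise, the cause was not tested.

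Over both sexes edgeR called 1 gene. DESeq2 called 29, limma with library weights 22, library totals 0, the tissue component 0 and the mitochondrial covariate 2. Without female mutant 3, DESeq2 called 53 and the weighted fit 4. Leaving out 1 library gave 0 to 2 genes, 2 without female mutant 3 (Mpeg1 and 2900052N01Rik) and 0 without each other library. In females, where edgeR called 0 genes (2127 at an unadjusted p under 0.05, limma-voom 0), DESeq2 called 6, library weights 4 and no filter 2, and without female mutant 3 DESeq2 called 15 and the weighted fit 1. In males, where edgeR called 0 genes (501 at an unadjusted p under 0.05, limma-voom 0), DESeq2 called 4, library weights 1 and the mitochondrial covariate 1. Without female mutant 3, DESeq2 called 16 in males and the weighted fit 1. Leaving out 1 library gave 0 to 1 in males, the 1 being Mpeg1 without female mutant 3. For the interaction, where edgeR called 0 genes (1381 at an unadjusted p under 0.05, limma-voom 0), DESeq2 called 4, library weights 1, no filter 1 and DESeq2 without female mutant 3 called 4. Leaving out 1 library gave 0 to 1, the 1 being Trdn without female mutant 6. For sex, edgeR called 7, DESeq2 12 and DESeq2 without female mutant 3 called 13.

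Of the 4 lists called by camera's preset, 0 were called with an estimated correlation, with or without female mutant 3. Leaving out 1 library gave 1 to 10 lists: 1 without female mutant 1, 2 without male wild-type 8, male mutant 10 or male wild-type 12, 7 without female wild-type 4 or male mutant 27, 8 without female mutant 3, 9 without female wild-type 2 and 10 without female mutant 6. Over the alternatives the adjusted p ran from 2.96e-16 to 0.636 for striatal markers, 1.30e-04 to 0.261 for channels, 0.0173 to 0.636 for microglia markers and 0.00227 to 0.739 for stress genes.

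With female and male effects compared across genes, the correlation was -0.122. It reversed with library weights (0.0682), with the mitochondrial covariate (0.0712), and without female mutant 3 in DESeq2 (0.0256) and the weighted fit (0.0854). It moved to -0.00581 with no filter and -0.228 with the CPM filter. Leaving out 1 library gave -0.180 to 0.0466, with 0.0204 without female mutant 3, 0.0466 without male wild-type 8 and -0.0489 without male mutant 10.

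Of 56 gene results named, 1 changed sign: Ncor1 stood at -0.00569 with the mitochondrial covariate. A further 25 that edgeR did not call were called in some alternative. Mpeg1 over both sexes kept its direction in 25 alternatives and its call in 12, with a log2 fold change of -1.11 to -0.98 over all 25. Depth limits genes at low levels in female mutant 3, where a count of 0 allows up to 1.16 CPM.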

Other observations

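The tests of list means by permutation and the permutation test of imprinted genes were chosen only after the results were seen, and the genes in the next paragraph were chosen after their values were seen.

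Outside the rule for naming genes, the histamine-degrading enzyme gene Hnmt (log2 fold change -0.28) and the provisional genes Gm32122 (1.48) and 2900052N01Rik (0.999) joined Mpeg1 as the 4 genes called over both sexes by DESeq2 and by limma with library weights, with and without female mutant 3. EdgeR's adjusted p was 0.950 for Hnmt, 0.577 for Gm32122 and 0.809 for 2900052N01Rik. Of the genes called in some of those 4 fits, the complement gene C1ra stood at -1.24 and the lectin pathway protease gene Masp1 at -0.57, each called in 3. The complement gene C4b, at 0.40, was called in 1. The astrocyte gene Gfap (0.49) and the GABA-synthesis gene Gad1 (-0.34) were each called in 1. Complement genes were not a fixed list and were not tested as a set.

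The mean log2 CPM of each of the 30 lists was compared between genotypes by exact permutation within sex (400 labellings, two-sided). The smallest p was that of the channels (difference -0.12, SE 0.03, exact p = 0.01, adjusted p = 0.3). Microglia markers gave -0.19 (SE 0.10, exact p = 0.025, adjusted p = 0.33), which was -0.09 without female mutant 3, glutamate receptors -0.06 (SE 0.02, exact p = 0.035, adjusted p = 0.33) and stress genes an exact p of 0.98. By this permutation 0 of 30 lists had an adjusted p under 0.05, against 4 by camera's preset and 0 with its estimated correlation. The smallest exact p that this permutation can give is 0.005 (2 of 400 labellings). Adjusted over 30 lists, no list could pass 0.05 alone at that p, so the permutation's count of 0 decides little.

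Since Dlk1, Zim1 and Cdkn1c stood among the genes of smallest p, the hypothesis was tested that imprinted genes may be higher in mutants as a class, on 30 others of which 29 were tested. Of these, 25 were higher, with a median log2 fold change of 0.22, and camera's preset gave p = 3.02e-07 (0.0245 with an estimated correlation, and 2.40e-05 with the preset without female mutant 3). Peg10 (0.68), Nnat (0.62), Zdbf2 (0.32) and Nap1l5 (0.41) had an unadjusted p under 0.05, and edgeR's adjusted p was 0.950 for each. An exact permutation of the list mean gave p = 0.075 (30 of 400 labellings, two-sided; difference 0.17, SE 0.09). Only Dlk1, Zim1 and Cdkn1c were left out of the list, so members that may share their regulation need not be independent of them or of one another. Since the preset called at least 4 of the fixed lists in 86 of 100 splits of these samples, its p alone does not decide, and the hypothesis stays open.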
